A study of Mus musculus with 3 samples.

How the data were processed

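The series comprises 3 libraries (RNA, T cell receptor and hashtag) made from 1 pool of TCRb+ CD90.2+ T cells sorted from mouse flank tumors, as the labels state. Per the labels' protocols, cells of Mcrs1ox and control tumors were stained with hashtag antibodies after sorting, loaded on a 10x Chromium instrument and made into libraries. Per the submitters' processing notes, bcl2fastq, Cell Ranger 7.1.0, Seurat 4.0.5 and the mouse build GRCm38 were used; the role of each is not given in the sources used here. The RNA and hashtag measurements were not used here. A deposited note by the authors gives 1 hashtag for each tumor group, but none of the 31 columns of the receptor table assigns a barcode to a hashtag. The planned comparison of the groups was therefore not made, and the library was treated as 1 sample. For 1 hashtag per tumor group the plan held no test, only the values of both groups with exact binomial intervals. An exact permutation test over animals or hashtags was planned for other designs. No p-value was computed, because cells and clonotypes of 1 library are not replicates.

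Per the file headers, the deposited table is a Cell Ranger list of all assembled receptor contigs, from called cells or not, with the count of UMIs (captured molecules) and the count of reads per contig as the authors' raw, unnormalized values. Per the file headers, the deposited table also gives the contig length, in bases. It names the V, D, J and constant segments, the CDR3, whether a contig is productive, whether its barcode was called as a cell, and a clonotype for the barcode. The table held 73145392 reads on 367096 UMIs. Called barcodes numbered 6139 and uncalled ones 8383. Productive contigs of called barcodes had 190.9 reads per UMI. The number of UMIs sets the precision, with a median of 22 productive UMIs per called barcode and 8 at the 10th percentile.

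The analysis used productive contigs named TRA or TRB of called barcodes, all of which the authors' table marks as of high confidence. Contigs of called barcodes that were not productive (7528 of 20725) entered no receptor, nor did the uncalled barcodes; both are described in the closing section. Receptor chains of a barcode were counted by distinct CDR3 nucleotide sequence, and the chain with the most UMIs stood for the barcode in segment use. Clonotypes are those of the authors' table, which can join cells of different TRB chains. An expanded clonotype has 2 or more cells and a large one 10 or more. A segment's share is the share of clonotypes that use it, each clonotype counted once by the commonest segment among its cells. The iNKT receptor was TRAV11 or TRAV11D with TRAJ18, with TRBV13-1, TRBV13-2, TRBV13-3, TRBV29 and TRBV1 as usual partners. The MAIT receptor was TRAV1 with TRAJ33, with TRBV19, TRBV13-2 and TRBV13-3 as usual partners. The jointly named TRBV12-2+TRBV13-2 was counted with TRBV13-2 in these lists and in the Vbeta8 family, a choice made after its sequence had been checked. A barcode with 2 productive TRB or 3 productive TRA chains was treated as a possible doublet, kept in the main values and left out in an alternative. No doublet caller was run. No called barcode held 3 or more productive chains of a kind; whether the authors' processing set this limit is not given in the sources used here.

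Shares have exact Clopper-Pearson 95% binomial intervals (SciPy), and a share of 0 has the upper limit that 3 counts of the total would give. Both cover counting error only: cells of a clonotype stem from 1 ancestor and are not independent draws of mice or tumors. The classes of expanded and single clonotypes were compared by whether their intervals overlap. The text names segments and receptors by a rule fixed before the data were examined. Named are the 6 TRBV, 3 TRBJ, 6 TRAV and 4 TRAJ segments with the highest share of clonotypes. Up to 10 segments whose intervals differ between expanded and single clonotypes are named too. The rule adds the detected members of the fixed lists. These are superantigen-linked TRBV, the Vbeta8 family, TRBV listed as pseudogenes, TRAV near the TRAJ cluster, and the D and constant segments. Last come the 10 largest clonotypes. A chain of such a clonotype is named if it was found in at least 5% of its cells.

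Positions are those of GENCODE M21 on GRCm38, the build that the submitters' notes name, matched by segment name. To check the names, the V region of the commonest contig of each V name (from the start of its framework 1 to the end of its framework 3) was searched in the GENCODE transcripts. For 20 of 22 TRBV names and 88 of 89 TRAV names the sequence was found in the transcript of the same name. Contigs named TRBV10 matched Trbv4, and those named TRBV12-2+TRBV13-2 matched Trbv13-2. The TRAV name left had no exact match. For 24 of the TRAV names, TRAV4D-4 and TRAV11 among them, the sequence was also found in the transcript of another segment, so that the sequence does not tell these copies apart and a position holds for the name alone.

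The functions were tested on simulated data: 5 simulated libraries of 3000 clonotypes, with planted expanded cells, planted second TRB chains, a V segment used by 20% of expanded and 5% of single clonotypes, and 20 planted pairs of clonotypes with matching receptors. Expanded cells and second TRB chains were recovered exactly in 5 of 5 runs, and the planted segment was found in 5 of 5. Of 575 comparisons of other segments, 6 had intervals apart. Between 18 and 20 of the 20 planted pairs were found per run.

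Alternatives fixed beforehand were contigs of 2 or more UMIs only, no possible doublets, other definitions of a clonotype, no largest clonotype, clonotypes counted once, 3 or more cells as expanded, and contigs that are not productive for the gamma-delta chains. Splitting clonotypes by their TRB chain, naming V segments by sequence and leaving out a TRAJ21 receptor family were added after seeing the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.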

Results

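T cells were recovered from subcutaneous flank tumors of mice, grown for 4 weeks after injection of 1000000 tumor cells in 100 uL, and sorted as TCRb+ CD90.2+ lymphocytes, that is, alpha-beta T cells. The tumors belonged to 2 groups, labelled Mcrs1ox and control in a study of pancreatic cancer, and the cells were marked with hashtag antibodies, 1 hashtag per tumor group, before they were loaded together. The series has 3 libraries from this pool (RNA, T cell receptor and hashtag), each present once. The receptor library is described here, as 1 sample without replicates. All intervals are exact Clopper-Pearson 95% intervals, cover counting error only and say nothing about the spread between mice.

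The receptor library held 40988 assembled receptor contigs from 14522 barcodes, with 367096 UMIs. Cells were called in 6139 barcodes, which carried 215998 of these UMIs and 13197 productive contigs of the alpha chain (TRA) or the beta chain (TRB). The median called barcode had 22 productive UMIs, with 13 and 35 at the quartiles. A productive TRB contig rested on a median of 13 UMIs and a productive TRA contig on 7.

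The first question was how complete the receptors of the sorted cells were. Both chains were found in 5428 of 6139 cells, or 88.4% (87.6 to 89.2). A TRB chain alone was found in 582 cells, 9.48% (8.76 to 10.2), whose median was 10 UMIs on TRB against 14 in cells with both chains and 1 TRB chain. A TRA chain alone was found in 129 cells, 2.10% (1.76 to 2.49). The cells had been sorted on the beta chain, which can set these shares. Productive chains of the gamma-delta receptor were found in 0 of 6139 cells. Contigs named as delta chain (TRD), none of them productive, were present in 67 cells, 1.09% (0.847 to 1.38), and all of them carried the alpha constant segment TRAC. No contig of any barcode, called or not, was named as gamma chain or had a gamma segment, so the library gives no measure of gamma-delta T cells.

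A second productive TRA chain, which T cells can carry because the TRA locus is not closed after the first rearrangement, was present in 1089 of 5428 paired cells, 20.1% (19.0 to 21.2). By clonotype size, this share was 22.0% (20.3 to 23.8) for 1 cell, 12.7% (10.7 to 15.0) for 2 to 4 cells, 15.6% (12.7 to 18.8) for 5 to 9 cells and 23.1% (21.1 to 25.1) for 10 or more, where 166 of the cells belonged to the largest clonotype. A second productive TRB chain, which allelic exclusion normally prevents, was present in 541 paired cells, 9.97% (9.18 to 10.8). The share with 2 TRB chains was 17.1% (15.5 to 18.7) among paired cells of single-cell clonotypes and 2.89% (2.15 to 3.79) among those of clonotypes of 10 or more cells. Because clonotypes are defined by the chains of a barcode, a barcode with a further chain can form a clonotype of its own, and part of this difference can come from the definition. Cells with 2 TRB chains had a median of 38 productive UMIs, a sum that includes the further chain, against 21 in cells with 1 TRB chain. The TRB chain with most UMIs, in the former the higher of 2 values, had a median of 17 UMIs in paired cells with 2 TRB chains and 14 in those with 1.

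The tumor-infiltrating T cells were clonally expanded. The cells fell into 3248 clonotypes, groups of cells with the same receptor as the authors' Cell Ranger output defines them. Of these, 555 had 2 or more cells and held 3446 cells, 56.1% (54.9 to 57.4). The 60 clonotypes of 10 or more cells held 1814 cells, 29.5% (28.4 to 30.7), and the 10 largest held 974 cells, 15.9% (15.0 to 16.8). At the other end, 2693 clonotypes consisted of 1 cell. The 367 largest clonotypes held 50% of the cells.

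**Figure D1:**
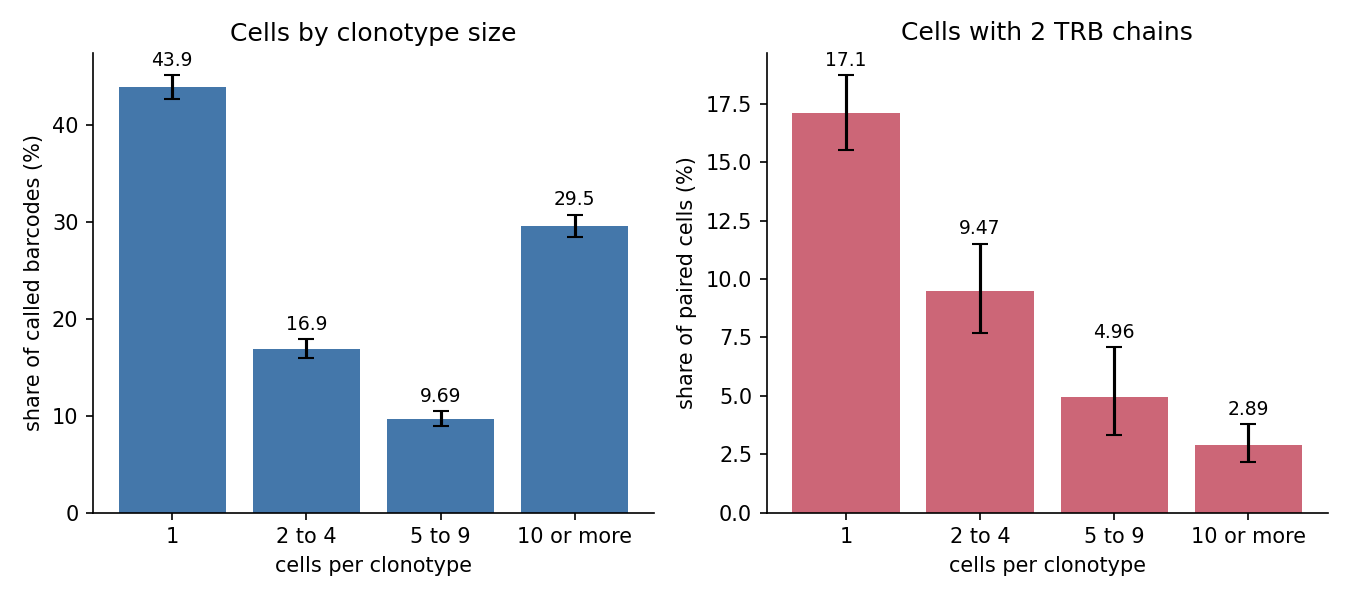
Left, the share of called barcodes (%) in clonotypes of each size. Right, the share of paired cells (%) with 2 productive TRB chains by the size of their clonotype. Bars are shares of the 1 pooled library and lines their exact 95% binomial intervals: clonotypes of 10 or more cells held 29.5% of cells, and 2.89% of their paired cells had 2 TRB chains, against 17.1% in single-cell clonotypes, a difference to which the definition of a clonotype by its chains can contribute.

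The largest clonotype had 203 cells, 3.31% of all cells (2.87 to 3.78). Of these, 184 carried the TRB chain TRBV15 to TRBJ1-4 with the CDR3 (the loop that contacts the antigen) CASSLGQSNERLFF. The other 19 carried another TRBV15 chain, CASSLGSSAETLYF with TRBJ2-3, so that this clonotype joins cells of different TRB chains. Both kinds shared the TRA chain TRAV12D-3 to TRAJ5 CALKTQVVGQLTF, found in 193 of the cells, and 176 had the further TRA chain TRAV14D-1 to TRAJ16 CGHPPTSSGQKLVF. The second clonotype, with 155 cells (2.52%, 2.15 to 2.95), paired TRBV13-3 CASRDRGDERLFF with TRAV14D-2 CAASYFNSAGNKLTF. The third, with 117 cells, paired TRBV13-3 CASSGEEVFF with the TRA chains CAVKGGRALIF (113 cells) and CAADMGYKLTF (112 cells), both of TRAV3D-3. The fourth, with 97 cells, paired TRBV13-1 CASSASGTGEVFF with TRAV10 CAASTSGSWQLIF (95 cells) and with TRAV15-1-DV6-1 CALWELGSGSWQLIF (28 cells). The fifth and the sixth, with 88 and 79 cells, shared the TRA residues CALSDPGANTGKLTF (TRAV12-2 to TRAJ52), and both used TRBV3 with TRBJ1-3, with the CDR3s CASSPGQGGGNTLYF and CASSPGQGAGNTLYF. The seventh (72 cells) had TRBV3 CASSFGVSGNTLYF with TRAV7D-2 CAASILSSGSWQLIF, and the eighth (63 cells) TRBV12-1 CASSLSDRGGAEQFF with TRAV6-1 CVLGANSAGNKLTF. The ninth (55 cells) had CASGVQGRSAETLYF, of a V segment named jointly as TRBV12-2+TRBV13-2, with TRAV4D-4 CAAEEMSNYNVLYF, and the tenth (45 cells) TRBV20 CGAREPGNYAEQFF with TRAV7D-2 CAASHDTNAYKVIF.

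The TRB locus lies on chromosome 6 between 40891229 and 41558452 (GRCm38, GENCODE M21). With each clonotype counted once, the V segments used most were TRBV12-2+TRBV13-2 (8.85% of 3154 clonotypes, 7.88 to 9.89), TRBV3 (8.28%), TRBV16 (6.91%), TRBV5 (6.88%), TRBV19 (6.85%) and TRBV13-1 (6.50%). The J segments used most were TRBJ2-7 (20.4%, 19.0 to 21.8), TRBJ2-1 (13.2%) and TRBJ2-3 (10.8%). The TRAV segments lie on chromosome 14 between 52427928 and 53977678, and the TRAJ and constant segments between 54155005 and 54224206. TRA use was spread more widely: the leading TRAV segments were TRAV6-6 (4.24% of 2829 clonotypes, 3.53 to 5.05), TRAV16N (3.43%), TRAV7D-2 (3.39%), TRAV12-2 (3.18%), TRAV4D-4 (3.15%) and TRAV3D-3 (3.04%), and the leading TRAJ segments TRAJ31 (5.20%), TRAJ22 (5.16%), TRAJ23 (4.60%) and TRAJ21 (4.52%). The CDR3 was 13.7 ± 1.38 residues long in TRA (SD, n = 2829 clonotypes) and 14.04 ± 1.43 in TRB (SD, n = 3154 clonotypes).

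The next question was whether expanded clonotypes used other segments than clonotypes of 1 cell in the same library. Intervals of the 2 classes did not overlap for 5 of 165 segments. The segment named TRBV10 was used by 8.47% (6.29 to 11.1) of 555 expanded clonotypes and 5.19% (4.37 to 6.12) of 2599 single ones. TRBJ2-3 (chromosome 6, 41543223 to 41543271) was used by 15.0% (12.1 to 18.2) of expanded and 9.97% (8.84 to 11.2) of single clonotypes, and TRAV4D-4 (chromosome 14, 52990866 to 52991389, or, with the same V sequence, Trav4n-4 at 53302036 to 53302559) by 5.24% (3.54 to 7.44) of 553 expanded and 2.64% (2.02 to 3.38) of 2276 single clonotypes. In the other direction, TRBV12-1 (chromosome 6, 41113550 to 41114067) was used by 2.70% (1.52 to 4.42) of expanded and 5.27% (4.44 to 6.20) of single clonotypes, and TRAV11 (chromosome 14, 53519303 to 53519859, or, with the same V sequence, Trav11d at 52824357 to 52824912), the V segment of invariant natural killer T cells, by 0.181% (0.00458 to 1.00) and 1.76% (1.26 to 2.39). Without the clonotypes of a TRAJ21 receptor family described among the observations, which were left out after seeing the data, 1 segment was left, TRAV11. TRBV10, TRBJ2-3 and TRAV4D-4 then no longer stood apart. For TRAV4D-4 this follows from the definition of the family, whose TRA chains are mostly TRAV4D-4. Of 29 expanded TRAV4D-4 clonotypes, 5 were left. TRBV12-1 hardly moved, with 2.84% (1.60 to 4.63) of expanded and 5.28% (4.45 to 6.22) of single clonotypes, whose intervals then overlapped. In simulated libraries, 6 of 575 comparisons of segments other than the planted one had intervals apart. This is not an exact chance rate for the library. The planted segment made the other TRBV segments slightly rarer among expanded clonotypes, and segments were otherwise drawn evenly.

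**Figure D2:**
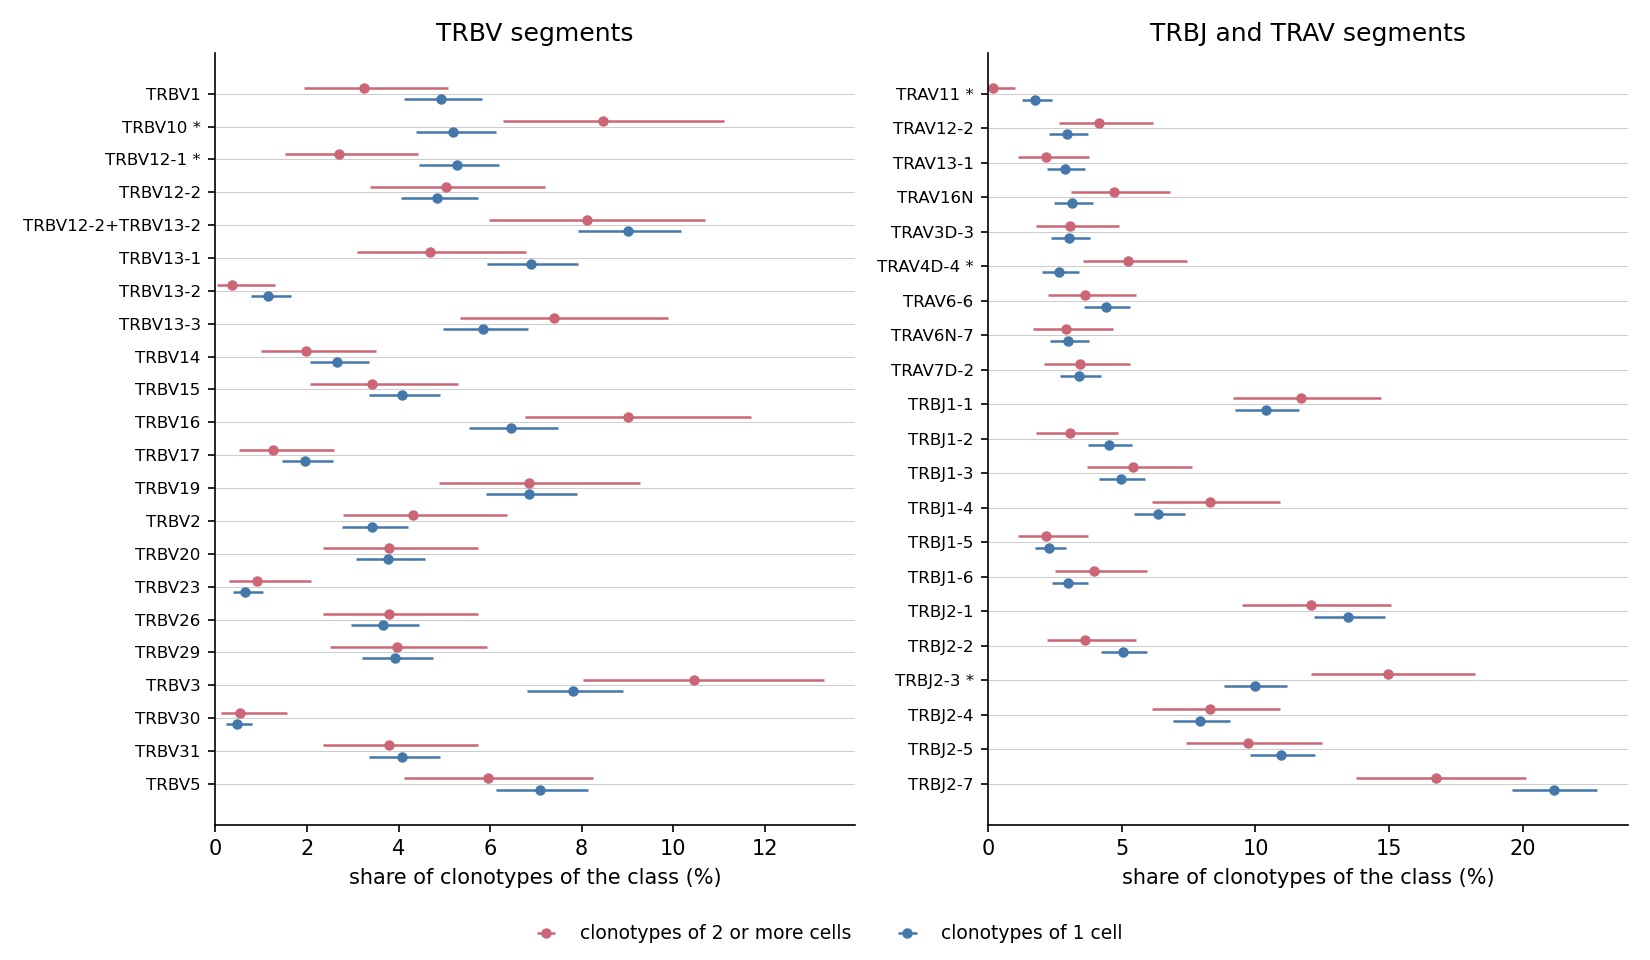
The horizontal axis gives the share (%) of clonotypes of 2 or more cells (red) and of 1 cell (blue) that use each TRBV and TRBJ segment, the most used TRAV segments and TRAV11. Points are shares, lines exact 95% binomial intervals, and asterisks mark segments whose intervals do not overlap, such as TRBJ2-3 at 15.0% against 9.97%.

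Among the segment lists fixed before the data were examined, TRBV10 and TRBV12-1 were the members whose intervals were apart. The V segments whose T cells are deleted in mouse strains with certain endogenous retroviral superantigens (TRBV12-1, TRBV12-2, TRBV15, TRBV16 and TRBV26) were all present. Together they made up 24.3% (22.8 to 25.8) of clonotypes, 24.0% of the expanded and 24.3% of the single ones, with TRBV16 at 6.91%, TRBV12-2 at 4.88%, TRBV12-1 at 4.82%, TRBV15 at 3.96% and TRBV26 at 3.68%. The Vbeta8 family (TRBV13-1, TRBV13-2 and TRBV13-3, with the jointly named segment counted here) made up 22.5% (21.03 to 24.0) of clonotypes, 20.5% (17.3 to 24.1) of the expanded and 22.9% (21.3 to 24.6) of the single ones. TRBV13-3 alone stood at 6.12% and TRBV13-2 under its own name at 1.01%. Of the listed TRAV segments near the TRAJ cluster, 4 of 5 were seen, together 2.93% (2.34 to 3.62) of clonotypes. They made up 1.99% (0.997 to 3.53) of the expanded and 3.16% (2.48 to 3.97) of the single ones. These were TRAV19 at 1.34%, TRAV21-DV12 at 1.31%, TRAV17 at 0.247% and TRAV18 in 1 clonotype. TRAV22 and TRAV23 lie nearer the TRAJ cluster but were not on the list. The fixed list of 13 TRBV pseudogene names differs from GENCODE. It holds TRBV21, which GENCODE gives as a gene, and leaves out TRBV24, which GENCODE gives as a pseudogene. Of the 13 names on it, 1 was seen, TRBV10. All 419 productive contigs so named carried a V region equal, base for base, to GENCODE's Trbv4 (chromosome 6, 41059394 to 41059886), whose own name did not occur in the library. GENCODE lists Trbv4 as a gene and Trbv10 as a pseudogene. The commonest V region of the contigs named TRBV12-2+TRBV13-2 was that of Trbv13-2 (chromosome 6, 41121396 to 41121832). The constant segment was TRBC1 in 39.7% (38.5 to 40.9) and TRBC2 in 60.0% (58.8 to 61.2) of 6551 TRB contigs, each joined to J segments of its own cluster throughout, and TRAC in 99.6% of 6646 TRA contigs. A D segment was named in a minority of TRB contigs, TRBD1 in 18.5% and TRBD2 in 7.24%.

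Invariant receptors mark innate-like T cells by their rearrangement. Invariant natural killer T (iNKT) cells, which see lipids on CD1d, join TRAV11 to TRAJ18. Such a chain was found in 40 of 5428 paired cells, 0.737% (0.527 to 1.00). Their TRA CDR3 was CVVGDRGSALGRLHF in 39 of the 40 cells, encoded by 4 different nucleotide sequences. Of these cells, 34 used a beta chain usual for iNKT cells (85.0%, 70.2 to 94.3), against 31.1% (29.9 to 32.4) of the other paired cells, and 18 of them used TRBV12-2+TRBV13-2. The 40 cells were 40 different clonotypes, so that no iNKT cell belonged to an expanded clonotype, which allows a share of up to 7.50% of these cells. Without possible doublets, 33 of these cells were left. The others had 2 TRB chains and can form clonotypes of their own by definition. Mucosal-associated invariant T (MAIT) cells, which see microbial riboflavin metabolites on MR1, join TRAV1 to TRAJ33. Such a chain was found in 19 paired cells, 0.350% (0.211 to 0.546), with the CDR3 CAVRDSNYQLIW in 14 of them. With contigs of 2 or more UMIs only, it was found in 13 of 5226 paired cells, 0.249% (0.133 to 0.425). Some of the 19 receptors thus rested on a chain of 1 UMI. A usual MAIT beta chain was present in 10 of the 19 (52.6%, 28.9 to 75.6), against 23.2% (22.1 to 24.4) of the other paired cells, so the intervals were apart. Because each of these cells was nearly always its own clonotype, counting clonotypes once raised both shares, to 1.46% for iNKT and 0.695% for MAIT receptors.

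The comparison the study names, T cells of Mcrs1ox tumors against those of control tumors, was not analysed here. None of the 31 columns of the receptor data names a hashtag, and no cell was assigned to a tumor group by any other means. All values above therefore describe the T cells of both groups together.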

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

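The test of free RNA in uncalled barcodes and the test of TRB pairs seen in 1 barcode were chosen only after the values they rest on had been seen; the tests of complete receptors were added after the other values of uncalled barcodes were known. Uncalled barcodes, which enter no comparison above, held 41.2% of all UMIs. Of the 1566 uncalled barcodes with a productive chain of 3 or more UMIs, 1301 held at least 2 such TRB chains, 83.1% (81.1 to 84.9), against 8.58% (7.89 to 9.31) of called barcodes, and 650 held at least 3. These barcodes were rich in receptor RNA, with a median of 62 productive UMIs. The median was 22 in called barcodes and 38 in called barcodes with 2 TRB chains. The uncalled barcodes were picked for at least 2 TRB chains of 3 or more UMIs each, which by itself raises the sum. The comparison therefore cannot decide about free RNA in droplets without a cell. A receptor was taken as complete where a TRB chain came with a TRA chain that called barcodes pair with it. With 1 complete receptor set aside in each barcode that had one, 52.4% (49.5 to 55.3) of the 1193 other TRB chains known from called barcodes still had such a TRA chain, against at most 3.69% in 1000 draws that exchanged the TRA chains left among barcodes, which argues against 1 cell with free RNA of others. At least 2 complete receptors were present in 495 barcodes, against at most 24 in the draws, which is consistent with several cells in 1 barcode. Why they were not called as cells is not given in the sources used here, and no biological explanation was tested.

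Called barcodes with 2 productive TRB chains, 541 in all, fell into separate kinds. There were 7 TRB pairs each seen in 3 or more barcodes, 68 barcodes together. In 1000 draws of random cell pairs there were at most 4 such TRB pairs. This argues against 2 cells in 1 barcode as the source of all 7. That count clears no single pair, because draws alone gave up to 4. Of the 68 barcodes, 4 had 2 TRA chains, 5.88% (1.63 to 14.4), against at least 77.0% in draws of random cell pairs. Since 36 of the 68 barcodes carried the same TRB pair, this value speaks mostly for that pair. The TRB pair of TRBV1 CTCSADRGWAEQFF and TRBV10 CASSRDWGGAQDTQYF recurred in 36 barcodes, with medians of 19.5 and 10.5 UMIs, and the pair of TRBV19 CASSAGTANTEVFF and TRBV19 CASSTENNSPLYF in 12. Both may be clones that carry 2 in-frame TRB rearrangements; whether both reach the surface was not measured. Of the 457 barcodes whose TRB pair was seen once, 54.3% (49.6 to 58.9) had 2 TRA chains, between the 15.3% (14.3 to 16.2) of barcodes with 1 TRB chain and the 77.0% that was the lowest value in draws of random cell pairs, so for these 2 cells in 1 barcode cannot be told apart from other sources, because the value lies between both references.

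Nonproductive contigs enter no comparison above. A nonproductive TRA contig was present in 31.5% of called barcodes and a nonproductive TRB contig in 13.4%. A nonproductive TRD contig was present in 1.09%, and of these 67 contigs 51 were joined to a TRAJ segment and all 67 carried the constant segment TRAC.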

How the results depend on the processing

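Of 58 alternative values, 36 stayed within the interval of the main value (for counts, within 1.5 times) and 22 did not. The number of clonotypes (2737 to 3331, against 3248) stayed within that range under each alternative run. With contigs of 2 or more UMIs only, the paired share was 85.1%, by the loss of weak chains. Without possible doublets, the paired share was 87.3%, dual TRA 17.1%, dual TRB 0% (by construction), expanded cells 57.9%, large clonotypes 31.5% and the 10 largest 17.4%. By the TRB chain alone, expanded cells were 62.0% and large clonotypes 32.7%. By paired CDR3 bases, expanded cells were 58.6% and the largest clonotype 2.49%; by paired residues, expanded cells were 58.9%, large clonotypes 30.8% and the largest 2.49%. For these definitions the cause was not tested. Without the largest clonotype, expanded cells were 54.6%, large clonotypes 27.1% and the 10 largest 13.6%. Counting clonotypes once gave 1.46% iNKT and 0.695% MAIT receptors, since the denominator shrinks. Any TRD contig, productive or not, gave 1.09%. Chosen after seeing the data, splitting clonotypes by TRB chain gave 54.3% expanded cells, and leaving out the TRAJ21 family gave 1 segment with intervals apart, against 5. Of the 4 calls lost, that of TRBV12-1 ended with its shares nearly in place (2.84% of expanded and 5.28% of single clonotypes, against 2.70% and 5.27%). Under the other alternatives, V names by sequence among them, that number was 4 to 6. Using all productive contigs changed nothing, because 0 contigs of called barcodes lack high confidence. Leaving out hashtags was not run, since barcodes are not assigned to them. No paired analysis was possible because the library is 1 sample. Depth limits how completely chains are counted: a productive TRA contig rested on a median of 7 UMIs, and the minimum of 2 UMIs lowered the paired share as given.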

Other observations

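The receptor families and the matching pairs were noticed in the data. The tests of chance pairing and of base errors were chosen only after the values they rest on had been seen. A family of receptors was built on TRA chains that join TRAJ21 (chromosome 14, 54198790 to 54198846) with a CDR3 of the pattern CAAE..SNYNVLYF, where a point stands for any residue. It held 255 cells, 4.15% of called barcodes (3.67 to 4.68), in 54 clonotypes of which 26 were expanded, with 17 different TRA CDR3s such as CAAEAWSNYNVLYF and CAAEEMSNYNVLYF. The TRA chains came from TRAV4D-4 and its near copy TRAV4-4-DV10. Among cells with 1 TRB chain, the family had 38 different TRB chains, of which 37 used TRBJ2-3 (97.4%, 86.2 to 99.9), against 9.70% (8.51 to 10.99) of other TRB chains, and 32 used the segment named TRBV10 (84.2%, 68.7 to 94.0), against 4.96% (4.10 to 5.94). The rest included the ninth clonotype, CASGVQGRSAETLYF, with 55 cells, and TRBV5 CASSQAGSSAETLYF, with 36 cells. Without the family, TRBJ2-3 was used by 10.8% (8.26 to 13.7) of expanded and 9.28% (8.19 to 10.5) of single clonotypes, and TRBV10 by 5.10% (3.39 to 7.34) and 4.50% (3.74 to 5.38), so that neither stood apart. TRAV4D-4 was used by 0.949% (0.309 to 2.20) and 1.65% (1.16 to 2.26), which follows from the family's definition by TRA chains that are mostly TRAV4D-4. TRBV12-1, at 2.84% (1.60 to 4.63) and 5.28% (4.45 to 6.22), also ceased to stand apart, though its shares hardly moved.

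A second family shared the TRA CDR3 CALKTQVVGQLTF, of TRAV12D-3 and TRAJ5, in 2 nucleotide versions. It held 223 cells, 3.63% of called barcodes (3.18 to 4.13), most of them in the largest clonotype. All 221 of its cells with 1 TRB chain used TRBV15. They carried 9 different TRB chains, so TRBV15 made up 100% (66.4 to 100) of the family's TRB chains, against 3.10% (2.43 to 3.90) of other TRB chains. Of the 9 chains, 5 used TRBJ2-3, among them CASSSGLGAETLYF with 10 cells and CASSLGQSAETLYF with 6, and 4 used TRBJ1-4. In the largest clonotype, the 19 cells with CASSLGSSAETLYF differed from the 184 with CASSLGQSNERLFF in their nonproductive rearrangements as well: 13 of the 19 carried a nonproductive TRAV4D-4 to TRAJ4 contig and 12 a nonproductive TRBV1 to TRBJ1-1 contig, each found in 0 of the 184 cells, which allows up to 1.63%.

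Near-identical TRB chains often had matching TRA chains. Of 75 pairs of expanded TRB chains with the same segments and at most 1 residue of difference, 23 carried TRA chains that match by the same rule (30.7%, 20.5 to 42.4), against at most 4 in 1000 random re-pairings, which argues against chance pairing of common chains. They formed 15 groups, whose TRB chains were carried by 456 cells, whatever their TRA chain, or 9.33% (8.53 to 10.2) of the 4887 cells with a TRA and 1 TRB chain. Of the 16 pairs whose TRB chains differ by 2 or more bases, 18.8% (4.05 to 45.6) had the same TRA bases. This interval counts the pairs as independent, though pairs of a group share chains. In 1 group, 4 TRB chains with 4 TRA base versions gave several of the 23 pairs. The true upper bound can thus be higher, and the test cannot decide whether one clone was split by base errors. For the 7 pairs that differ by 1 base, the value of 42.9% (9.90 to 81.6) rests on too few pairs and leaves such errors open. Free RNA of a larger clone is argued against by the TRA depth of the smaller members, a median of 7 UMIs with a lower quartile of 6. Besides base errors, selection of like receptors by a shared ligand remains open as a hypothesis, which no value here tests.

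The fifth and the sixth clonotype, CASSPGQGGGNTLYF and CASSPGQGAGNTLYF, belong to these groups and had the same TRA bases. A nonproductive TRBV13-2 to TRBJ2-1 contig was found in 52 of 79 cells with the latter TRB chain and this TRA chain (65.8%, 54.3 to 76.1) and in 0 of 88 with the former, which allows up to 3.41%. The latter TRB chain was carried by 103 cells with 1 TRB chain in all, some of them with another TRA chain.

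In expanded clonotypes with 2 productive TRA chains, the TRAJ segments of both chains tended, by the median, to lie nearer each other than in random re-pairings. The median distance was 6.15 kb over 62 clonotypes in which the pair of TRA chains was seen in 2 or more cells, below the 7.89 to 16.6 kb of 1000 random re-pairings, with a median of 11.999 kb. This is consistent with the hypothesis that both TRA alleles rearrange to neighbouring TRAJ segments in step, whose prediction was written before the distance was computed. Over a wider set of 334 clonotypes, with 1 TRA pair each, the median was 8.34 kb against 14.1 kb, and never below 11.7 kb, in re-pairings. This set leaves out some clonotypes with 2 TRA chains, since single-cell clonotypes alone held 481 paired cells with 2 TRA chains.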
